A study of Mus musculus with 3 samples.

How the data were processed

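The material was the lateral ventricle choroid plexus of mice at baseline and after 24 h and 72 h of 3% DSS in drinking water, 5 mice pooled per library, sequenced as single cells with 3' tag libraries. Per the submitters' processing notes, reads were processed with Cell Ranger (version not stated) and Seurat 3 on genome build mm10. The authors' annotation of 8 cell classes was used as deposited.

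The plan assumed raw counts, but the deposited table named as counts holds depth-corrected values, a score with no fixed unit: its column sums equal the corrected total in all 17705 cells and the UMI total in 2. The other deposited table holds the natural log of 1 plus that score in all values compared. The deposited metadata give the count of UMIs and of genes per cell. UMI counts per gene and cell were therefore back-calculated by inverting the SCTransform correction, with a mean, slope and dispersion fitted per gene. A whole count gave back 99.998% of the 16975 genes by cells exactly, and 83.3% of values allow only 1 count. In cells below 16000 UMIs the median recovered total was 100% of the deposited one, and above it remaining ambiguity was settled by the expected count. Per library, 99.7% to 99.9% of UMIs were recovered. All levels rest on these recovered counts.

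UMIs were summed per class and library and scaled to CPM. Ratios add a pseudocount of 10 CPM, so they are smaller than ratios of CPM for weak genes, and a printed ratio of a named gene is that of CPM with its exact conditional interval. A gene counted as apart with 20 UMIs or more in 1 of both libraries and a ratio of at least 2 or at most 0.5, a rule of size and not a test. The number from counting error was simulated 100 times. For 33 gene lists fixed before the data were examined, the median log2 ratio of members with 20 UMIs or more was placed among 10000 random lists matched on mean CPM in 20 bins, and a list in the outer 2.5% at either end was taken as high or low, which is a description of these libraries. Shares carry Clopper-Pearson intervals and levels exact Poisson intervals. Zeros were set against a floor of 3 UMIs of the class total per library. Gene positions come from GENCODE vM21, in which 98.6% of symbols had 1 entry.

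Named genes were chosen by a rule fixed before the data were examined: per main class and DSS time the 5 highest and 5 lowest ratios among genes with at least 50 UMIs and 50 CPM in 1 library and a mean CPM of at least 0.2 of that in the class where the gene is highest, without mitochondrial, ribosomal, Gm, Rik, haemoglobin, Xist and Y-linked genes. To these come the highest and lowest member of each list and each measured study gene. Not every gene the rule picks is named in the text. All 4 main classes had 50 cells or more per library. The genes named among the 10 epithelial ones that were 2-fold apart fall partly outside it, as do genes of the closing section, and were named after their values were seen.

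Alternatives fixed beforehand were pseudocounts of 1 and 50, no minimum and 100 UMIs, median-of-ratios scaling, a total without the 50 most abundant epithelial genes, the mean over cells, thinning to the smallest total, cells with 1000 UMIs or more, own Leiden clusters (resolution 1, 30 components, 15 neighbours), cells marked by Scrublet, and the deposited log values. Scrublet's automatic threshold marked 22 of 17705 cells. The share among non-epithelial cells and plain ratios of CPM were also fixed beforehand. Added after the data were seen were the depth window of 2000 to 16000 UMIs (16000 or more for epithelial cells), cells with 2000 UMIs or more, macrophage-marker cells, the mean of deposited corrected counts, and leaving out the expected share of highest Scrublet scores (5.55% of cells). That share was set per library and grew with its cell number.

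The methods were tested on simulated data. Of 792 simulated class sums 88.4% came back within 5% of the truth, with a median of 99.9%. The simulation used genes that had fitted closely and a constant rate per class and library, as the recovery assumes. It therefore does not show how variation between cells of a class affects the recovery. Of 200 genes changed 2-fold the size rule took 6 in epithelial and 60 in immune cells, and of 200 changed 3-fold it took 184 and 187, since the pseudocount shrinks ratios. Of unchanged genes it took 0 in epithelial and 23 to 65 in immune cells. The 95% ratio interval covered the truth in at least 95.7% of draws. Of random lists, 7% fell in the outer 2.5% at either end, against 5% by construction. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 and leidenalg 0.10.2. The embedding coordinates were not used.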

Results

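RNA of single cells was measured in the choroid plexus of the lateral ventricles, the tissue that makes cerebrospinal fluid and that separates blood from it, in male C57BL/6J mice. The mice drank water without or with 3% dextran sulphate sodium (DSS), a polymer that damages the lining of the colon and sets off colitis. There were 3 libraries, each from the pooled tissue of 5 mice: baseline, 24 h of DSS and 72 h of DSS. Each group had 1 library, so there are no replicates, no p-values are given, and a difference between libraries cannot be set against the spread between mice. Every interval below is a 95% interval that covers counting error only.

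The deposited tables held 4311 cells at baseline, 9392 at 24 h and 4002 at 72 h, although about 7000 cells were loaded for each library. The cells carried 101653448, 138204037 and 109141017 unique molecular identifiers (UMIs) in that order. The median depth was 29363 UMIs per cell at baseline, 6583.5 at 24 h and 35222 at 72 h. Cells with fewer than 2000 UMIs made up 33.1%, 36.8% and 26.5% of the libraries. Transcripts of 17 epithelial marker genes took 21.9%, 27.2% and 20.2% of all UMIs, and they were also found in cells of other classes. Whether free RNA or cells captured together brought them there was not tested.

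The first comparison asks whether the cell classes of the tissue changed in number under DSS. The 24 h library held larger shares of endothelial and immune cells and a smaller share of epithelial cells than the libraries before and after it. By 72 h these shares were back near their baseline values. The 24 h library was also the shallowest and held more cells than were loaded, and many of its endothelial and immune cells were shallow.

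Epithelial cells were 79.7% of the cells at baseline (exact Clopper-Pearson interval 78.4 to 80.8), 67.0% at 24 h (66.0 to 67.9) and 83.0% at 72 h (81.8 to 84.2). Endothelial cells were 3.94% (3.38 to 4.57), 9.21% (8.63 to 9.81) and 4.15% (3.55 to 4.81). Immune cells were 2.41% (1.98 to 2.92), 6.58% (6.09 to 7.10) and 2.65% (2.17 to 3.19). Mesenchymal cells, the fibroblasts of the stroma, were 2.53% (2.08 to 3.04), 2.89% (2.56 to 3.24) and 3.12% (2.61 to 3.71). Smooth muscle cells were 0.603%, 0.905% and 0.625%, and the class annotated as ependymal was 0.997%, 0.362% and 0.30%. That class was mixed: astrocyte markers stood at 13038 CPM, 590.1 and 1779 in it and ependymal markers at 560.5, 5565 and 618.4, so its share does not count ependymal cells alone. The annotation left 6.17%, 9.11% and 4.12% in a mixed epithelial and mesenchymal class and 3.69%, 3.97% and 2.02% unnamed. Of the 865 endothelial cells at 24 h, 474 had fewer than 2000 UMIs, and of the 618 immune cells 285 did. Among cells with 2000 UMIs or more, endothelial cells at 24 h were 6.59% and immune cells 5.61%.

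**Figure D1:**
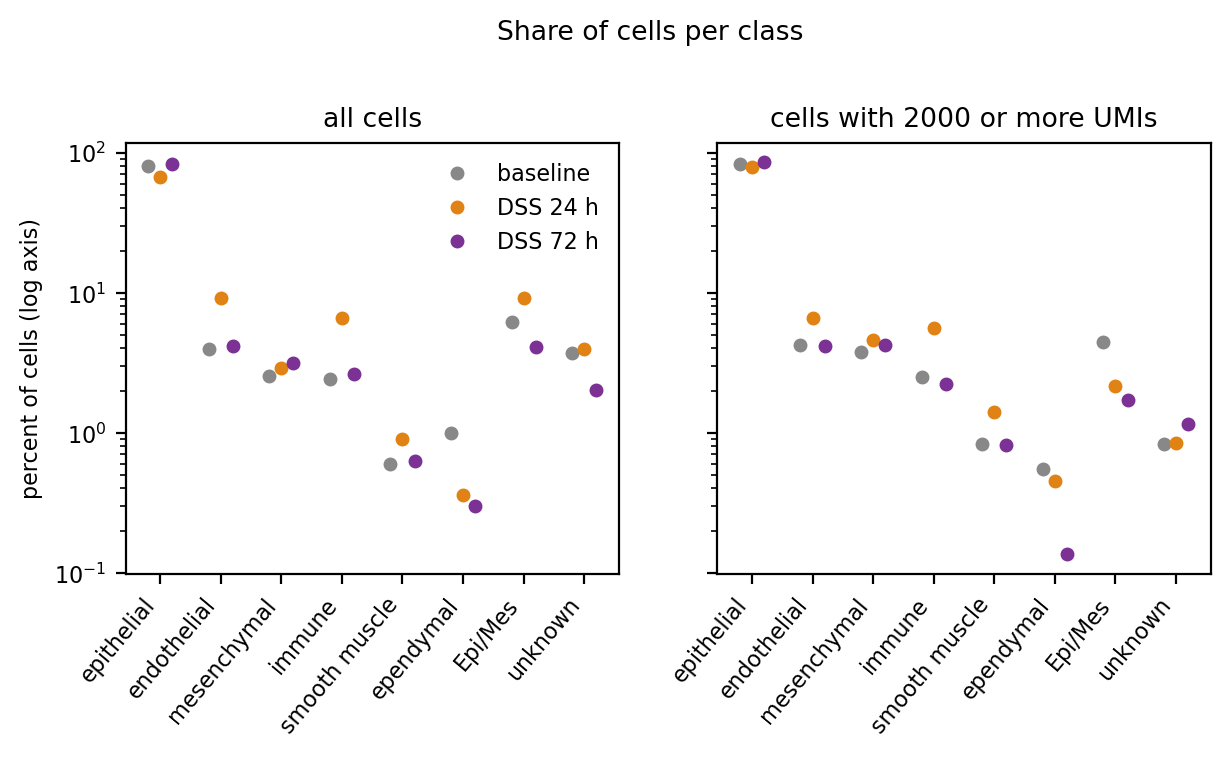
Share of cells per class in percent (log axis) for the 3 libraries, over all cells at left and over cells with 2000 UMIs or more at right. Each point is 1 library. Endothelial cells at 24 h stand at 9.21% of all cells and at 6.59% of the deeper cells.

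The series title names a vascular barrier of the choroid plexus that closes during intestinal inflammation, so the endothelial comparison asks what the vessel cells expressed. Choroid plexus capillaries are fenestrated, and Plvap encodes the diaphragm protein of their openings, while Cldn5 encodes the tight junction claudin of closed brain capillaries. Plvap made up a larger part of endothelial RNA at both DSS times when all cells were summed, but not at 24 h among cells of 2000 to 16000 UMIs, and so did endothelial markers in general. Cldn5 was lower at both times, and most of its UMIs were in endothelial cells without Plvap. Interferon and leukocyte adhesion genes were higher over all cells but not among cells of that depth range.

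Plvap (ENSMUSG00000034845.6, chromosome 8, 71497765 to 71511752 in GRCm38) was at 458.7 CPM (UMIs scaled to a common class total) at baseline, 951.5 at 24 h and 922.4 at 72 h. Its ratio to baseline was 2.07 at 24 h (exact interval 1.95 to 2.20) and 2.01 at 72 h (1.88 to 2.15). The 14 endothelial markers, Plvap among them, together went from 4307 CPM to 6823 and 7611 in the class. Part of the difference in Plvap was thus shared by endothelial RNA in general. High Scrublet scores, as doublets have, were found in 1.18%, 18.4% and 3.01% of endothelial cells. High meant the top scores of each library up to a quota that grew with its cell number. The quotas were 149 of 4311 cells at baseline, 706 of 9392 at 24 h and 128 of 4002 at 72 h. Part of the difference between libraries was therefore set by the quota and not by a common score. Scrublet's automatic threshold marked 0 endothelial cells in each library. Endothelial cells with 16000 UMIs or more numbered 59, 95 and 53 and weighed heavily in the sums over all cells. Those with 2000 to 16000 UMIs held 392298 of 2945140 class UMIs at baseline, 1841697 of 5300620 at 24 h and 475493 of 2442910 at 72 h. They carried less epithelial RNA, 1.88%, 6.22% and 1.83% of UMIs against 11.1%, 15.3% and 6.92% in all endothelial cells. In this depth window, which was chosen after the depths had been seen, Plvap stood at 2014 CPM, 2048 and 2845, a ratio of 1.02 at 24 h and 1.41 at 72 h, and the 14 markers at 17301, 14069 and 19775. The list of fenestrae, caveolae and VEGF receptor genes had a median log2 ratio of 0.59 at 24 h and 0.86 at 72 h over all cells, with 7 of 13 and 13 of 13 members at least 1.5-fold higher. In the window its median was -0.20 at 24 h and 0.31 at 72 h, and as a mean over cells it was -0.50 at 24 h, so its direction at 24 h depended on which cells were counted and how they were weighted.

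Cldn5 (ENSMUSG00000041378.2, chromosome 16, 18776847 to 18778262) fell from 150.6 CPM at baseline to 41.2 at 24 h and 60.5 at 72 h, the lowest ratio of the ranked endothelial genes at both times (0.274, interval 0.232 to 0.322, and 0.402, 0.331 to 0.485). In the depth window it went from 703.5 CPM to 52.1 and 84.1. Endothelial cells without a Plvap UMI, 37 at baseline, 292 at 24 h and 31 at 72 h, held 94.9%, 72.3% and 72.8% of its UMIs. Among Plvap-positive cells of the window it was at 17.4 CPM from 6 UMIs at baseline, 23.8 at 24 h and 37.1 at 72 h. The blood-brain barrier list was at -0.10 and 0.07 over all cells and at -0.59 and -1.0 in the window, at percentiles 0.07 and 0 of random lists. The 6 Plvap-negative window cells at baseline carried 270 of the 276 UMIs of Cldn5, 70 of 74 of Spock2, 63 of 68 of Slco1a4 and 50 of 61 of Slc2a1. The fall of Cldn5 and the low medians in the window thus rest largely on few baseline cells.

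**Figure D2:**
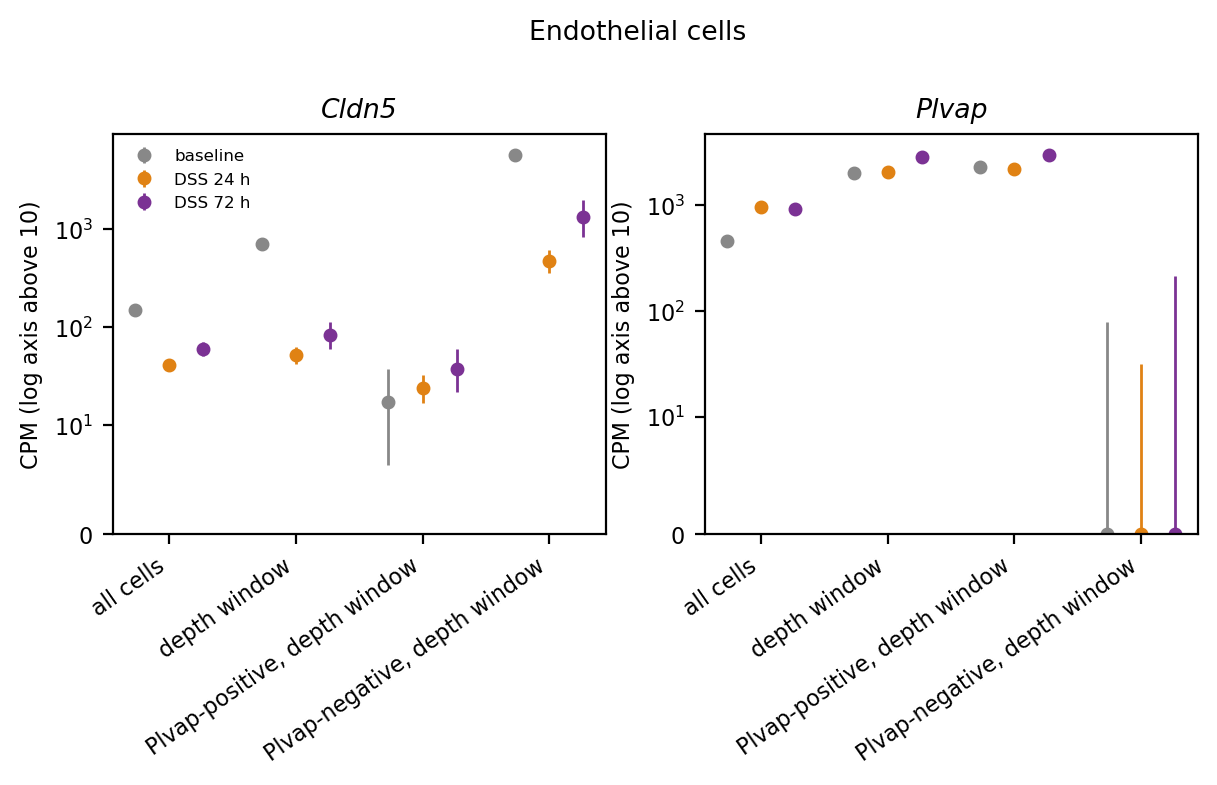
CPM of Cldn5 and Plvap in endothelial cells of the 3 libraries, with exact Poisson 95% intervals (vertical axis logarithmic above 10), in all cells, in the depth window of 2000 to 16000 UMIs, and in its Plvap-positive and Plvap-negative cells. Cldn5 in the window stands at 703.5 CPM at baseline and at 52.1 and 84.1 under DSS, while in Plvap-positive cells it stands at 17.4, 23.8 and 37.1. At baseline 6 Plvap-negative cells hold 270 of the 276 Cldn5 UMIs of the window.

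Cdh5, the adherens junction cadherin, had ratios of 1.70 and 1.96, but 0.954 and 1.26 in the window. The ratios of Ctnnb1 were 0.905 and 1.08, those of Lef1 0.641 and 0.804, those of Axin2 0.843 and 0.638. Icam1 had 0.803 and 0.938 and Vcam1 0.828 and 1.12. Il1b went from 9.46 CPM to 4.58 at 24 h and 0 at 72 h, at least 7.70-fold lower against a floor of 3 UMIs, at levels near the floor. Its direction at 24 h turned in the window and as a mean over cells. The 14 macrophage markers also went down in the class, from 51.5 CPM to 38.8 and 9.28. Whether the Il1b UMIs came from endothelial cells was not tested. The list of Wnt pathway genes was at -0.10 and 0.25, the study genes as a list at -0.26 and -0.08, and none of these 4 medians lay in the outer 2.5% at either end of random lists.

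The number of endothelial genes at least 2-fold apart from baseline was 113 at 24 h (49 higher, 64 lower) and 97 at 72 h (88 higher, 9 lower), with 0 in simulated libraries that differed by counting error alone. The split by direction depended on the cells and their weights: in the window it was 159 higher and 102 lower at 24 h and 69 and 57 at 72 h, and as a mean over cells 48 and 319 at 24 h and 132 and 104 at 72 h. At 24 h the highest ranked genes were Tsc22d3 (ratio 4.08), Mfap2 (4.0), Ly6a (2.89), AW112010 (3.04) and Rbp7 (3.03), and in the window their ratios were 3.66, 2.37, 1.31, 1.56 and 1.65. Below Cldn5, the lowest were Scd2 (0.368), Fads2 (0.325), Fads1 (0.361) and Slc16a6 (0.367), with 0.701, 1.38, 0.818 and 0.533 in the window, where every interval reached 1. At 72 h the highest were Rgs5 (2.95), Fry (3.69), Trp53i11 (3.15), Ebf1 (2.48) and Ptprb (2.4), while 12 markers of pericytes and smooth muscle, Rgs5 among them, went from 750.2 CPM to 1170 and 2227 in the class. The lowest after Cldn5 at 72 h were Ppp1r1a (0.408), Hspa1b (0.504), Slc16a6 (0.508) and Clu (0.555). The interferon list was at 0.49 and 0.42 over all cells and at -0.06 and -0.08 in the window. Leukocyte adhesion genes were at 0.61 and 0.76, and at -0.37 and 0.0604 in the window. Arterial genes were at 0.44 and 0.67, MHC class I genes at 0.64 and 0.48, and in the window arterial genes were at -0.14 and -0.11 and MHC class I genes at -0.0738 and 0.0281.

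Epithelial cells, which secrete cerebrospinal fluid, were the most deeply covered class. At both DSS times they carried less RNA of heat shock genes and of the unfolded protein response, the programs that handle misfolded protein. At 24 h they also carried less RNA of ion and water transporters, which was back at baseline by 72 h. Medians of inflammatory and interferon genes were close to 0, although all 4 lay in the outer 2.5% of random lists.

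The count of epithelial genes at least 2-fold apart from baseline was 10 of 14414 at 24 h and 0 of 14195 at 72 h. At 24 h it was 7 higher and 10 lower with the total without 50 epithelial genes, and 18 and 56 with a pseudocount of 1. Of the 10, Hbb-bs, a haemoglobin gene, was the only higher one. In the depth window 0 genes were higher and 10 lower, so Hbb-bs was not among them there. The lower ones over all cells included AY036118, Gm42418, Herpud1, Hspa1b, Lars2, Sec61a1, mt-Atp8 and mt-Nd3. AY036118, Gm42418 and Lars2 were lower at 24 h in all 8 classes and not in epithelial cells alone. Gm42418 went from 1008 to 257.1 CPM in epithelial cells and from 5141 to 1745 in mesenchymal cells. Lars2 went from 39.6 to 6.42 and from 75.1 to 24.3. Herpud1, which acts in disposal of misfolded protein (ENSMUSG00000031770.16, chromosome 8, 94386438 to 94395377), went from 223.0 CPM to 102.3 and 138.9, ratios of 0.459 (0.449 to 0.469) and 0.623 (0.610 to 0.636). Heat shock genes had medians of -0.47 and -0.34, with 5 and 4 of 12 members at least 1.5-fold lower and none that much higher, and with median-of-ratios scaling the first was -0.26 with 3 lower. Dnajb1 was the lowest ranked gene at 72 h, at 99.5 CPM against 174.8 at baseline. The unfolded protein response list had medians of -0.29 and -0.26, of which the first was -0.0826 with median-of-ratios scaling, with Xbp1 at a ratio of 0.610 and Manf at 0.715 at 72 h. Ion and water transport genes were at -0.47 at 24 h, with 6 of 21 at least 1.5-fold lower and Clic6 lowest (703.6 to 390.9 CPM), and at 0.03 at 72 h. With median-of-ratios scaling the 24 h median was -0.31, with 1 of 21 that much lower. In an own clustering many epithelial cells of 24 h lay apart from the others: 3 clusters held 2470, 802 and 708 cells at 24 h against 12, 26 and 1 at baseline, and 2 clusters 14 and 11 against 623 and 593. Others were mixed, such as a cluster with 459 cells at baseline, 1853 at 24 h and 439 at 72 h, and another with 1001, 163 and 643. The 5 highest ranked genes at 24 h were Gt(ROSA)26Sor (2.16), Alyref (2.24), Pfn1 (1.70), Tm2d1 (1.70) and Skp1a (1.63), and Sec61a1 (0.384), Ddit3 (0.462) and Fads2 (0.458) were among the lowest with Herpud1. At 72 h no ranked gene exceeded a ratio of 1.39, that of Cirbp, followed by H1f0 (1.33), Erh (1.33), Cmtm8 (1.27) and Hnrnpd (1.24), and Chordc1 stood at 0.667. NF-kB targets were at 0.0257 (percentile 99.99 of random lists) and -0.0280 (0.11), and interferon genes at 0.0290 and 0.0504, both at percentile 100. Many of these genes are weak against the pseudocount of 10 CPM, and with a pseudocount of 1 the medians were 0.19 and -0.0992 for NF-kB targets and 0.0958 and 0.18 for interferon genes.

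Mesenchymal cells build the stromal matrix around the vessels. At 24 h genes of matrix remodelling and fibroblast activation were lower, and by 72 h the list was back at baseline. Heat shock genes were lower at both times. MHC class II genes rose from near 0, in a list with few measured members. Clock genes as a list were lower at 24 h, although Dbp, one of them, was higher at both times.

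The number of mesenchymal genes at least 2-fold apart was 108 at 24 h (51 higher, 57 lower) and 43 at 72 h (15 higher, 28 lower), against 1.01 and 1.75 from counting error alone. Epithelial markers took 1.12% of mesenchymal UMIs at baseline, 4.55% at 24 h and 0.865% at 72 h. Matrix remodelling genes had a median of -0.63 at 24 h, with 9 of 16 at least 1.5-fold lower, and -0.01 at 72 h. Ccn1 (ENSMUSG00000028195.4, chromosome 3, 145646976 to 145649981), a matrix protein induced by stretch, was the lowest member of that list at 24 h (172.7 to 68.4 CPM, ratio 0.396, 0.314 to 0.498). Ccn2 stood at 182.8 CPM at baseline and 60.8 at 72 h. Heat shock medians were -0.42 and -0.50. The clock list had a median of -0.39 at 24 h, with 3 of 13 members at least 1.5-fold lower, and 0.14 at 72 h. Dbp rose from 20.2 CPM to 70.1 at 24 h (ratio 3.47, 2.21 to 5.70) and 73.4 at 72 h, while Per1, another clock gene, had ratios of 0.487 and 0.511. Cd74, the class II invariant chain, had 6 UMIs or 5.36 CPM at baseline, 32.0 CPM at 24 h (ratio 5.97, 2.59 to 16.9) and 63.3 at 72 h (11.8, 5.21 to 33.1). List medians were 1.28 over 2 members and 1.41 over 3. In these cells 14 macrophage markers stood at 102.1, 55.7 and 82.7 CPM. In the depth window these markers rose alongside, at 46.0, 56.4 and 83.0 CPM. Also highest at 24 h were Cox8b (3.28), Ramp2 (2.26), Igfbp5 (2.14) and Tob1 (2.37), and lowest were AY036118 (0.178), Neat1 (0.368), Lars2 (0.324), Zyx (0.355) and Amotl2 (0.358). At 72 h Pgf (2.73), Crabp1 (2.46), Cxxc5 (2.31) and Cox8b (2.39) were higher and AY036118 (0.268), Zyx (0.399) and Tubb6 (0.371) lower. Fabp4 had a ratio of 0.372 at 72 h over all cells, but 2.16 in the depth window.

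The annotation has no macrophage class, so the comparison planned for macrophages was read in its immune class. At 24 h these cells carried less RNA of NF-kB targets, cytokines and chemokines. Cell division genes were higher at 24 h in the whole class but not among its macrophage-marker cells. At 72 h less RNA of T and natural killer (NK) cells was found in the class, and MHC class II genes were lower in the summed counts. Ptgs2, the enzyme behind inflammatory prostaglandins, was higher at 72 h.

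The number of immune genes at least 2-fold apart was 335 at 24 h (209 higher, 126 lower) and 291 at 72 h (252 higher, 39 lower), of which counting error alone gives 30.9 and 25.3. At 24 h lower genes were the majority in class sums thinned to the smallest total (49 higher, 163 lower), with a minimum of 100 UMIs (29 and 58) and with a pseudocount of 50 (12 and 30). Higher genes stayed the majority in the depth window (359 and 122), with a pseudocount of 1 (658 and 323), as a mean over cells (527 and 357) and without the highest Scrublet scores (447 and 176). Epithelial markers took 7.33%, 14.4% and 6.21% of immune UMIs, and 14 macrophage markers stood at 13377, 10044 and 13043 CPM in the class. NF-kB targets had a median of -0.75 at 24 h, with 14 of 23 at least 1.5-fold lower, and -0.08 at 72 h. In immune cells of the depth window with more macrophage than lymphocyte marker UMIs the median at 24 h was -0.61. Macrophage chemokines and cytokines were at -0.61 and -0.02, Ccl9 at a ratio of 0.214 (0.142 to 0.324) and Ccl7 at 0.374 at 24 h. Ccl8 went the other way, from 0 to 58.9 CPM, at least 9.27-fold higher against a floor of 3 UMIs. Other genes lowest at 24 h were AY036118 (0.164), Lilr4b (0.228), Tnip3 (0.279) and Bmp2 (0.248). The cell cycle list was at 0.51 at 24 h, but at 0.12 in macrophage-marker cells and at 0.19 as a mean over cells, both inside the range of random lists. Top2a was at 50.7 CPM at 24 h against 0 (at least 7.99-fold higher). At 72 h the list was at -0.67 with 3 of 16 members measured. MHC class II genes were at 0.05 and -0.38, and as a mean over cells at 0.0258 at 72 h. Ptgs2 (ENSMUSG00000032487.8, chromosome 1, 150100031 to 150108227) rose from 36.0 to 208.1 CPM at 72 h (5.78, 3.48 to 10.2), Cxcl10 from 40.2 to 149.5, and Nbeal1 (4.06), Idh1 (3.17) and Lifr (2.81) were also among the 5 highest. Fibroblast markers in the immune class stood at 298.4, 306.7 and 1174 CPM, so RNA of another cell type was also higher there at 72 h.

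Gzmb (118.2 CPM), Xcl1 (93.2), Trbc2 (66.0) and Napsa (59.7) had 0 UMIs at baseline and were at least 18.6-fold, 14.7-fold, 10.4-fold and 9.41-fold higher at 24 h. Nkg7 fell from 201.1 CPM to 0 at 72 h, at least 43.5-fold, and Gzma (0.166), Ccl5 (0.245), Ctla2a (0.222) and AY036118 (0.291) were lowest with it. Of 104 immune cells at baseline 12.5% had a UMI of 9 T and NK marker genes (6.83 to 20.4), of 618 at 24 h 12.5% (9.96 to 15.3), and of 106 at 72 h 3.77% (1.04 to 9.38). In epithelial cells, which should lack these genes, the shares were 0.844%, 0.827% and 0.933%, at median depths of 34746, 23976 and 38502 UMIs against 3644, 2446.5 and 4525 in immune cells. An own cluster of T and NK cells held 13, 74 and 6 cells. Thinned to 2000 UMIs per cell, the immune shares were 16.7%, 20.1% and 1.52%, and the epithelial ones 0.0837%, 0.0860% and 0.0795%. Marker sums in the class were 328.1, 468.0 and 21.0 CPM for T and NK cells, 262.2, 171.7 and 145.8 for B cells, and 15.2, 128.0 and 16.1 for dendritic cells.

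The last comparison asks which genes moved the same way at both DSS times. In endothelial cells 10 genes were higher and 2 lower at both, in mesenchymal cells 5 and 10, in immune cells 21 and 17, and in epithelial cells 0. Lists of these sizes drawn independently would share 0.422 and 0.0577, 0.0487 and 0.209, and 1.44 and 0.979 genes. Simulated unchanged libraries with a shared baseline gave at most 10 in immune cells, 1 in mesenchymal cells and 0 in endothelial cells. Both ratios use the one baseline library, and part of the excess may come from it.

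**Figure D3:**
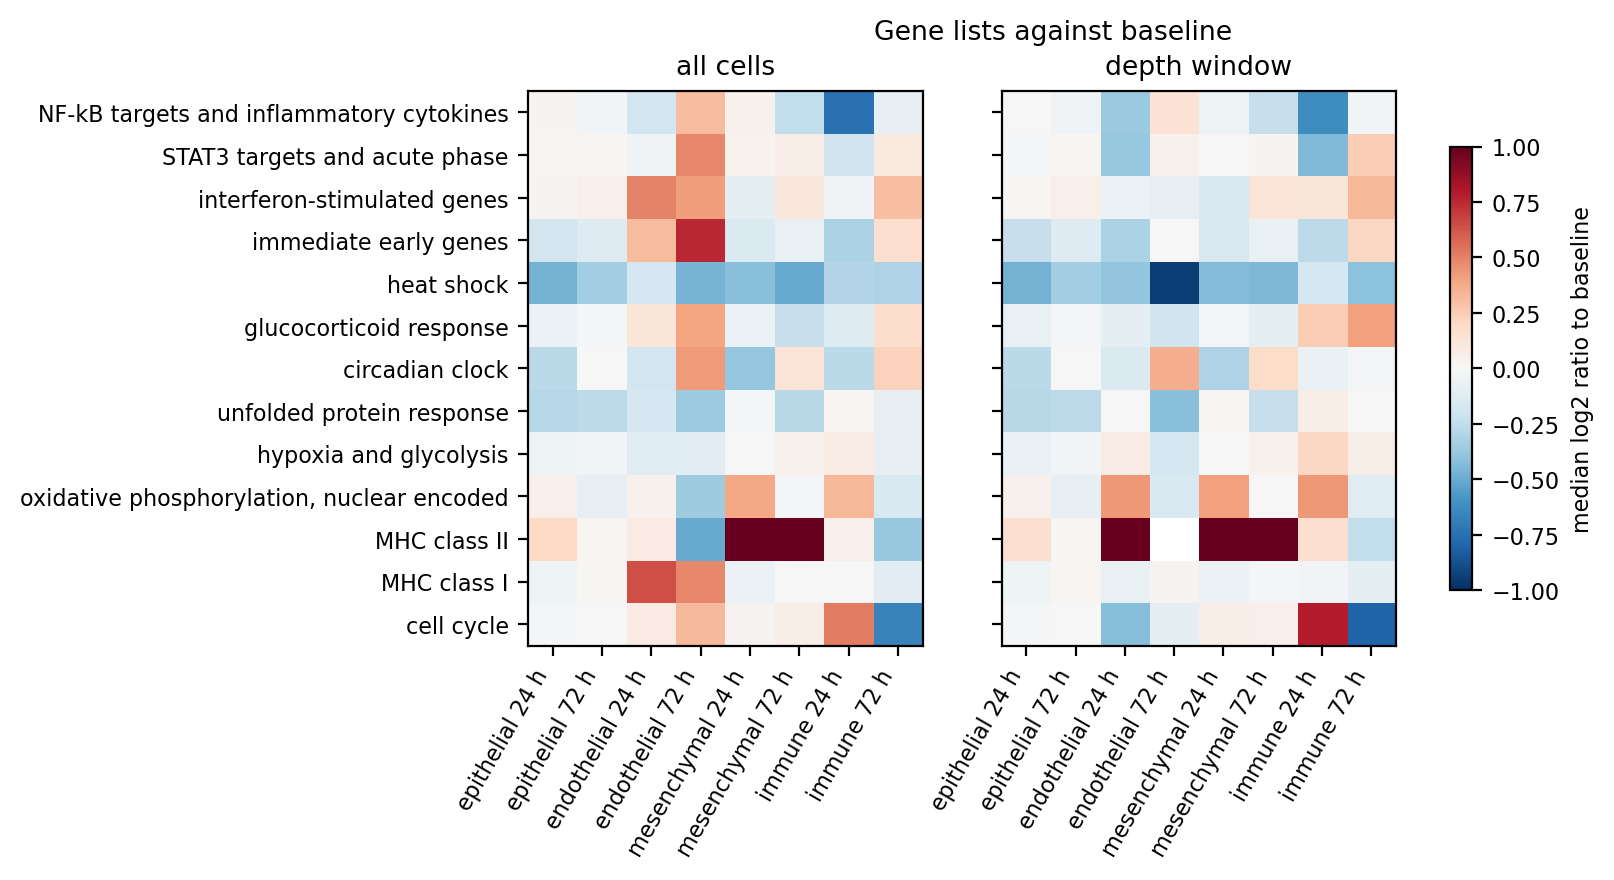
Median log2 ratio to baseline of 13 gene lists read in all 4 main classes, at 24 h and 72 h, over all cells and in the depth window (for epithelial cells, 16000 UMIs or more). Colours run from -1 to 1, values beyond are drawn at the ends, and the blank field had no measured member. Heat shock genes stand at -0.47 and -0.34 in epithelial cells and at -0.42 and -0.50 in mesenchymal cells.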

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

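The tests of Cldn5, of depth and of immediate early genes for heat shock, and of counting error for T and NK cells were chosen after the results they concern had been seen at least in part. The tests in smooth muscle cells and at thinned depth were written before their values were seen, but the thinning was repeated 51 times, in place of 1, after its first value had been seen.

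In 3 lists the median lay in the outer 2.5% of random lists on one side at 24 h and on the other at 72 h, and the difference between the times was not tested. Immune cells had immediate early genes at -0.32 at 24 h and 0.16 at 72 h, and the second value was -0.19 without the cells of highest Scrublet score. Cell cycle genes were at 0.51 and -0.67 in immune cells, the latter over 3 members, and the former was 0.12 in macrophage-marker cells. Epithelial NF-kB targets stood at 0.0257 and -0.0280, with no member 1.5-fold higher or lower.

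Cldn5 was lower in endothelial cells at both DSS times. The values argue against free epithelial RNA in shallow cells as the whole cause. In the depth window the ratio was 0.0741 at 24 h and 0.120 at 72 h, each with an interval below 1. These intervals cover the counting of UMIs and not which cells were caught, and 6 cells held 270 of the 276 baseline UMIs. Fewer brain capillary cells among the dissected vessels may account for it, but Plvap-positive cells cannot decide this. Their ratio was 1.37 at 24 h (0.578 to 3.95) and 2.14 at 72 h (0.804 to 6.62), over 6 of 276 window UMIs at baseline. Fewer brain capillary cells and less Cldn5 inside them would both leave Plvap-positive cells unchanged. Plvap-negative cells were 6 of 63 window cells at baseline, 28 of 296 at 24 h and 4 of 70 at 72 h. Brain tissue markers over all cells stood at 51.5, 21.4 and 25.2 CPM for astrocytes and 29.6, 15.7 and 24.99 for oligodendrocytes. An own cluster with astrocyte markers held 44, 4 and 9 cells. Cells with 3 or more UMIs of oligodendrocyte markers were 2.78% at baseline, 0.607% at 24 h and 3.77% at 72 h. Deeper cells pass this cutoff more easily. Epithelial cells alone held 1974, 1752 and 2157 UMIs of these markers and 2171, 2157 and 2184 of astrocyte markers. Levels over all cells therefore do not measure attached brain tissue alone. An effect of DSS on the brain capillary cells stays open. In Plvap-negative cells of the window Cldn5 fell from 5789 CPM (6 cells) to 470.5 (28 cells) and 1330 (4 cells). Other brain capillary genes fell with it there, Spock2 from 1501 CPM to 136.9 and 346.9 and Slco1a4 from 1351 to 205.3 and 173.5. A changed make-up of these cells and lower Cldn5 inside brain capillary cells cannot be told apart.

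Heat shock genes were lower under DSS, in the outer 2.5% at both times in epithelial and mesenchymal cells and at 72 h in endothelial and immune cells. A difference in depth is argued against: among epithelial cells with 16000 to 32000 UMIs the medians were -0.47 and -0.38, with intervals below 0. Smooth muscle cells, not used in the comparisons, had medians of -0.72 and -0.90, and the noncoding AY036118 was lower at both times in all 8 classes (48.7, 13.2 and 20.6 CPM in epithelial cells), so a difference between libraries that reaches every class may be at work, which an effect of DSS on the whole tissue would also give. Immediate early genes, which handling also induces, had an interval below 0 in 4 of the 6 class and time pairs with low heat shock genes and above 0 in 2. Handling and DSS cannot be told apart with 1 library per group.

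RNA of T and NK cells was lower among immune cells at 72 h. The share with a marker UMI was 3.77% against 12.5% at baseline, with overlapping intervals (upper limit 9.38, lower limit 6.83), and an own cluster of T and NK cells held 6 cells against 13. At 2000 UMIs per cell the intervals of the median thinning did not overlap, 1.52% (upper limit 8.16) against 16.7% (lower limit 8.92), which argues against a difference in depth. Immune cells at 72 h were also the deeper ones by the median, 4525 against 3644 UMIs. Counting error stays open, since thinning drops counts and gave 0 to 3 of 66 cells at 72 h and 10 to 13 of 72 at baseline. An effect of DSS and a difference in how much blood the tissue held were not tested.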

How the results depend on the processing

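The depth window, macrophage-marker cells, cells with 2000 UMIs or more, the mean of corrected counts and the high Scrublet scores were chosen after the data had been seen. The other alternatives were fixed before. Shares were compared with their counting intervals, list medians with intervals from Poisson draws, and counts with a limit of 1.5-fold. Ratios of genes include the pseudocount, except plain ratios of CPM and ratios of means of deposited logs or corrected counts. These were set against the interval of the ratio with the pseudocount. A ratio of mean logs is not a fold change. Where a value moved, the cause was not tested. The median of all genes shifted by up to 0.17 log2 between libraries in the summed counts, by -0.16 to 0.25 with a pseudocount of 1 and by -0.18 to 0.22 as the mean over cells.

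Shares stayed inside their counting interval in 74 of the values recomputed and left it in 58. Of these 58, 21 came from the non-epithelial denominator, which gives another quantity and leaves the interval by construction. The endothelial and immune shares were highest at 24 h under each alternative. Cells with 2000 UMIs or more gave epithelial shares of 82.8% at baseline, 78.4% at 24 h and 85.5% at 72 h. Cells with 2000 UMIs or more gave endothelial shares of 6.59% at 24 h. Cells with 2000 UMIs or more gave mesenchymal shares of 3.78% at baseline, 4.57% at 24 h and 4.25% at 72 h. Cells with 2000 UMIs or more gave immune shares of 5.61% at 24 h. Own Leiden clusters gave epithelial shares of 63.6% at baseline, 55.6% at 24 h and 70.5% at 72 h. Clusters of 1051, 859 and 472 cells that the naming rule left unnamed held 1028, 856 and 472 cells annotated as epithelial. Own Leiden clusters gave mesenchymal shares of 6.05% at baseline, 9.56% at 24 h and 5.92% at 72 h. Among the clusters named mesenchymal, those of 635 and 244 cells held 607 and 229 cells of the annotated mixed epithelial and mesenchymal class. Cells with 1000 UMIs or more gave epithelial shares of 69.3% at 24 h. Cells with 1000 UMIs or more gave endothelial shares of 8.26% at 24 h. Cells with 1000 UMIs or more gave mesenchymal shares of 3.44% at baseline and 3.96% at 72 h. Exclusion of high Scrublet scores gave epithelial shares of 69.0% at 24 h. Exclusion of high Scrublet scores gave endothelial shares of 8.13% at 24 h. The non-epithelial denominator gave endothelial shares of 19.4% at baseline, 27.9% at 24 h and 24.4% at 72 h. The non-epithelial denominator gave mesenchymal shares of 12.4% at baseline, 8.74% at 24 h and 18.4% at 72 h. The non-epithelial denominator gave immune shares of 11.9% at baseline, 19.9% at 24 h and 15.6% at 72 h.

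Counts stayed within 1.5-fold in 97 cases and moved in 50, and the count shared by both times moved in 4. Pseudocounts changed the counts by construction, since they set how weak a gene can be. Exclusion of high Scrublet scores gave endothelial counts of 273 at 24 h. Exclusion of high Scrublet scores gave immune counts of 623 at 24 h and 755 at 72 h. A pseudocount of 1 gave epithelial counts of 74 at 24 h, 5 at 72 h and 57 at 72 h against 24 h. A pseudocount of 1 gave endothelial counts of 646 at 24 h, 556 at 72 h and 598 at 72 h against 24 h. A pseudocount of 1 gave mesenchymal counts of 403 at 24 h, 166 at 72 h and 412 at 72 h against 24 h. A pseudocount of 1 gave immune counts of 981 at 24 h, 451 at 72 h and 1018 at 72 h against 24 h. A pseudocount of 50 gave epithelial counts of 3 at 24 h and 3 at 72 h against 24 h. A pseudocount of 50 gave endothelial counts of 19 at 24 h, 11 at 72 h and 8 at 72 h against 24 h. A pseudocount of 50 gave mesenchymal counts of 14 at 24 h, 7 at 72 h and 23 at 72 h against 24 h. A pseudocount of 50 gave immune counts of 42 at 24 h, 71 at 72 h and 78 at 72 h against 24 h. Counts shared by both times were 1 in endothelial cells, 2 in mesenchymal cells and 5 in immune cells under a pseudocount of 50. The total without 50 epithelial genes gave epithelial counts of 17 at 24 h, 3 at 72 h and 11 at 72 h against 24 h. The mean over cells gave epithelial counts of 2 at 72 h and 10 at 72 h against 24 h. The mean over cells gave endothelial counts of 367 at 24 h, 236 at 72 h and 712 at 72 h against 24 h. The mean over cells gave immune counts of 884 at 24 h, 492 at 72 h and 778 at 72 h against 24 h. Median-of-ratios scaling gave epithelial counts of 8 at 72 h against 24 h. Median-of-ratios scaling gave endothelial counts of 63 at 72 h and 53 at 72 h against 24 h. The depth window gave endothelial counts of 261 at 24 h and 350 at 72 h against 24 h. The depth window gave counts shared by both times of 34 in endothelial cells. A minimum of 100 UMIs gave mesenchymal counts of 50 at 24 h, 14 at 72 h and 49 at 72 h against 24 h. A minimum of 100 UMIs gave immune counts of 87 at 24 h, 35 at 72 h and 100 at 72 h against 24 h. Thinning to the smallest total gave immune counts of 212 at 24 h. No minimum gave immune counts of 694 at 72 h.

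Of the 57 list medians in the outer 2.5% at either end, median-of-ratios scaling kept the sign of 57, the pseudocounts of 1 and 50 kept 57 and 57, the mean over cells 48 and the depth window 46 of 56. Fewer stayed in the same outer 2.5%: 34 of 57 as the mean over cells, 34 of 56 in the depth window, 7 of 9 in macrophage-marker cells, 54 without high Scrublet scores, 55 with the total without 50 epithelial genes, 56 with a pseudocount of 1 and 57 under each other alternative. Giving each moved value for these 57 alone, and not for lists inside the range of random lists, was chosen after the number of moved values had been seen. In epithelial and mesenchymal cells the depth window kept most UMIs of the class. At baseline these were 91602861 of 93200500 and 1000242 of 1119470, and at 24 h 115908769 of 123934000 and 1790222 of 1872250. Medians kept there in the window thus say little about depth. Respiration stands for nuclear genes of oxidative phosphorylation. Endothelial medians at 24 h were 0.94 (fenestrae), 0.75 (arterial), 0.76 (leukocyte adhesion), 0.76 (interferon), 0.57 (immediate early) and 0.86 (MHC class I) under exclusion of high Scrublet scores. Immune medians at 24 h were -0.49 (immediate early) and 0.70 (respiration) under exclusion of high Scrublet scores. Immune medians at 72 h were -0.19 (immediate early), -0.80 (MHC class II) and -1.05 (cell cycle) under exclusion of high Scrublet scores. Endothelial medians at 72 h were 0.97 (fenestrae), 1.02 (arterial), 0.56 (interferon), 0.55 (circadian) and -1.08 (MHC class II) under a pseudocount of 1. Endothelial medians at 24 h were 0.76 (leukocyte adhesion), 0.73 (interferon) and 0.76 (MHC class I) under a pseudocount of 1. Epithelial medians at 24 h were 0.19 (NF-kB), 0.0761 (STAT3), 0.0958 (interferon), -0.49 (heat shock), -0.31 (unfolded protein), 1.04 (MHC class II) and -0.54 (ion transport) under a pseudocount of 1. Epithelial medians at 72 h were -0.0992 (NF-kB), 0.18 (interferon), -0.38 (heat shock), -0.28 (unfolded protein) and 0.0824 (tight junctions) under a pseudocount of 1. Mesenchymal medians at 24 h were 3.01 (MHC class II) under a pseudocount of 1. Mesenchymal medians at 72 h were 2.78 (MHC class II) under a pseudocount of 1. Endothelial medians at 24 h were 0.47 (fenestrae), 0.17 (arterial), 0.15 (leukocyte adhesion), 0.21 (interferon) and 0.38 (MHC class I) under a pseudocount of 50. Endothelial medians at 72 h were 0.61 (fenestrae), 0.25 (junctions), 0.34 (arterial), 0.34 (leukocyte adhesion), 0.34 (STAT3), 0.20 (interferon), -0.30 (respiration), -0.15 (MHC class II) and 0.32 (MHC class I) under a pseudocount of 50. Epithelial medians at 24 h were 0.00527 (NF-kB), 0.00627 (interferon), -0.33 (heat shock), -0.25 (unfolded protein), 0.0538 (MHC class II) and -0.36 (ion transport) under a pseudocount of 50. Immune medians at 24 h were -0.51 (NF-kB) and 0.20 (cell cycle) under a pseudocount of 50. Epithelial medians at 72 h were 0.0115 (interferon), -0.0725 (immediate early), -0.30 (heat shock), -0.22 (unfolded protein) and 0.0237 (tight junctions) under a pseudocount of 50. Mesenchymal medians at 24 h were 0.43 (MHC class II) and -0.43 (matrix remodelling) under a pseudocount of 50. Mesenchymal medians at 72 h were 0.53 (MHC class II) under a pseudocount of 50. The total without 50 epithelial genes gave endothelial medians at 72 h of 0.22 (junctions), 0.34 (interferon), 0.62 (immediate early), -0.61 (heat shock), -0.50 (unfolded protein) and -0.50 (respiration). The total without 50 epithelial genes gave epithelial medians at 24 h of 0.0589 (NF-kB), 0.0353 (STAT3), 0.0729 (interferon), -0.36 (heat shock), -0.18 (unfolded protein), 0.38 (MHC class II) and -0.41 (ion transport). The total without 50 epithelial genes gave epithelial medians at 72 h of 0.084 (interferon) and 0.0812 (tight junctions). Immune medians at 24 h were 0.43 (respiration) under the total without 50 epithelial genes. The mean over cells gave endothelial medians at 24 h of -0.50 (fenestrae), 0.0366 (arterial), -0.34 (leukocyte adhesion), -0.19 (interferon), -0.48 (immediate early) and -0.0138 (MHC class I). Endothelial medians at 72 h were 0.40 (fenestrae), 0.19 (arterial), 0.39 (leukocyte adhesion), -0.0573 (NF-kB), 0.24 (STAT3), 0.21 (interferon), 0.26 (immediate early), -0.81 (heat shock), -0.0896 (glucocorticoid), -0.27 (unfolded protein), -0.28 (respiration), 0.0905 (MHC class II) and 0.27 (MHC class I) under the mean over cells. Epithelial medians at 24 h were 0.11 (NF-kB), 0.0675 (STAT3), 0.0525 (interferon), -0.40 (heat shock), -0.35 (unfolded protein) and 0.88 (MHC class II) under the mean over cells. Epithelial medians at 72 h were -0.00279 (NF-kB), -0.10 (immediate early), -0.26 (heat shock), -0.0133 (respiration) and 0.0841 (tight junctions) under the mean over cells. Immune medians at 24 h were -0.88 (NF-kB), -0.62 (immediate early), 0.76 (respiration), 0.19 (cell cycle) and -0.83 (chemokines) under the mean over cells. Immune medians at 72 h were 0.0917 (immediate early) and 0.0258 (MHC class II) under the mean over cells. Median-of-ratios scaling gave endothelial medians at 24 h of 0.72 (fenestrae), 0.57 (arterial), 0.45 (immediate early) and 0.76 (MHC class I). Median-of-ratios scaling gave endothelial medians at 72 h of 0.72 (fenestrae), 0.21 (junctions), 0.35 (STAT3), 0.31 (interferon), 0.62 (immediate early), -0.60 (heat shock), -0.50 (unfolded protein) and -0.48 (respiration). Median-of-ratios scaling gave epithelial medians at 24 h of 0.0544 (NF-kB), 0.0264 (STAT3), 0.0568 (interferon), -0.26 (heat shock), -0.0826 (unfolded protein), 0.28 (MHC class II) and -0.31 (ion transport). Median-of-ratios scaling gave immune medians at 24 h of -0.21 (immediate early) and 0.45 (respiration). Median-of-ratios scaling gave immune medians at 72 h of 0.0566 (immediate early) and -0.49 (MHC class II). Median-of-ratios scaling gave mesenchymal medians at 24 h of -0.30 (heat shock) and 0.51 (respiration). Median-of-ratios scaling gave epithelial medians at 72 h of -0.27 (unfolded protein) and -0.0942 (respiration). The depth window gave endothelial medians at 24 h of -0.20 (fenestrae), -0.14 (arterial), -0.37 (leukocyte adhesion), -0.0575 (interferon), -0.32 (immediate early) and -0.0738 (MHC class I). The depth window gave endothelial medians at 72 h of 0.31 (fenestrae), 0.10 (junctions), -0.11 (arterial), 0.0564 (venous), 0.0604 (leukocyte adhesion), 0.0458 (STAT3), -0.0849 (interferon), 0.00699 (immediate early), -0.94 (heat shock), -0.20 (glucocorticoid), -0.15 (respiration) and 0.0281 (MHC class I). Epithelial medians at 24 h were 0.0061 (NF-kB), -0.017 (STAT3) and 0.16 (MHC class II) under the depth window. For the depth window, immune medians at 24 h came to 0.43 (respiration) and 0.78 (cell cycle). Immune medians at 72 h were -0.24 (MHC class II) under the depth window. Exclusion of cells marked by Scrublet gave immune medians at 72 h of 0.0704 (immediate early). Macrophage-marker cells gave immune medians at 24 h of 0.45 (respiration) and 0.12 (cell cycle).

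Among named genes 2215 ratios stayed inside their interval, 903 moved and 63 reversed. The moved ones include 206 from means of deposited logs, 172 from means of corrected counts and 79 from plain ratios of CPM. The reversed ones include 14, 7 and 0 of these. Endothelial ratios were 1.03 for Ctnnb1 at 24 h under exclusion of high Scrublet scores. Immune ratios were 1.05 for Atp5b at 24 h, 1.46 for Cox6c at 72 h and 1.07 for Pfkp at 72 h under exclusion of high Scrublet scores. Endothelial ratios were 0.987 for Ctnnb1 at 72 h under the total without 50 epithelial genes. Epithelial ratios were 0.987 for Dnah11 at 72 h, 0.933 for Il13ra1 at 72 h, 1.01 for Ldha at 72 h, 0.933 for Mcm6 at 72 h and 1.01 for Pim1 at 72 h under the mean over cells. Endothelial ratios were 1.06 for Ccl4 at 24 h, 0.759 for Cdh5 at 24 h, 0.836 for Hspb1 at 24 h, 1.17 for Il1b at 24 h, 0.925 for Ldha at 24 h, 0.741 for Tspan12 at 24 h, 0.845 for Abcg2 at 72 h, 0.959 for Ctnnb1 at 72 h, 0.983 for Klf6 at 72 h and 0.937 for Ndrg1 at 72 h under the mean over cells. Immune ratios were 1.13 for Atp5b at 24 h, 0.963 for Cebpd at 24 h, 1.05 for Cd74 at 72 h and 1.14 for Cox6c at 72 h under the mean over cells. Median-of-ratios scaling gave endothelial ratios of 0.988 for Ctnnb1 at 72 h. Endothelial ratios were 1.05 for Atp5a1 at 24 h, 1.09 for Ccl4 at 24 h, 0.954 for Cdh5 at 24 h, 1.06 for Cry2 at 24 h, 1.23 for Fads2 at 24 h, 0.911 for Hspb1 at 24 h, 1.1 for Il1b at 24 h, 1.01 for Nr2f2 at 24 h, 0.847 for Tspan12 at 24 h, 0.888 for Abcg2 at 72 h, 1.31 for Cd74 at 72 h, 0.904 for Gja4 at 72 h, 0.949 for Kdr at 72 h, 0.978 for Klf6 at 72 h, 0.87 for Ndrg1 at 72 h and 1.26 for Sdf2l1 at 72 h under the depth window. Mesenchymal ratios were 1.89 for Fabp4 at 72 h under the depth window. The mean of deposited logs gave endothelial ratios of 1.02 for Ccl4 at 24 h, 0.683 for Cdh5 at 24 h, 0.978 for H2-D1 at 24 h, 0.932 for Hspb1 at 24 h, 0.991 for Ier3 at 24 h, 0.981 for Ly6e at 24 h, 0.929 for Plvap at 24 h, 0.631 for Tspan12 at 24 h, 1.01 for Vcam1 at 24 h and 0.995 for Ctnnb1 at 72 h. The mean of deposited logs gave mesenchymal ratios of 0.996 for Fos at 24 h and 1.26 for Fabp4 at 72 h. The mean of deposited logs gave immune ratios of 1.00 for Atp5b at 24 h and 1.1 for Cd74 at 72 h. The mean of corrected counts gave endothelial ratios of 0.699 for Cdh5 at 24 h, 0.77 for Hspb1 at 24 h, 0.995 for Ly6e at 24 h, 0.895 for Plvap at 24 h and 0.65 for Tspan12 at 24 h. The mean of corrected counts gave immune ratios of 1.01 for Atp5b at 24 h and 1.06 for Cd74 at 72 h. Depth limits the counts in small classes: at 24 h counting error alone gives 30.9 genes in immune cells, 58.25 in endothelial and 82.33 in immune cells of the depth window and 99.66 in macrophage-marker cells.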

Other observations

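The 3 genes below were picked after their values had been seen and do not stand for their pathways. In epithelial cells they were lower at 24 h and back near baseline at 72 h. Fads1, a fatty acid desaturase, went from 145.6 CPM to 68.8 and 158.4 in epithelial cells, and Fads2, another desaturase, from 111.6 to 51.1 and 109.7. Hmgcs1, an enzyme of cholesterol synthesis, went from 212.9 CPM to 151.2 and 198.1 in epithelial cells and from 441.3 to 235.1 and 261.0 in mesenchymal cells, but from 73.3 to 79.1 and 97.9 in immune cells. A list of 26 sterol and fatty acid genes, also chosen afterwards and holding these 3, had medians of -0.46 and -0.092 in epithelial cells. It was at -0.71 and -0.26 in mesenchymal and -0.00336 and 0.45 in immune cells. Endothelial medians were -0.60 and -0.27 over all cells, but -0.039 and 0.14 in the depth window.

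The next genes, picked after their values were seen, differed between libraries in most classes at once, and Alyref and Gt(ROSA)26Sor were highest at 24 h. Alyref, a factor for export of messenger RNA, stood at 33.1, 74.1 and 34.7 CPM in epithelial cells and at 69.7, 146.6 and 78.7 in mesenchymal cells. Gt(ROSA)26Sor, a ubiquitous noncoding RNA, stood at 52.2, 112.6 and 53.5 in epithelial cells. AY036118, a noncoding transcript, instead set the baseline apart, with lower values at both DSS times, at 48.7, 13.2 and 20.6 CPM in epithelial cells and 709.1, 71.5 and 263.0 in smooth muscle cells.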
